A study of Arabidopsis thaliana with 12 samples.

How the data were processed

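Transcript abundance was measured on 12 Affymetrix ATH1 arrays of Arabidopsis thaliana, each hybridised with RNA from roots per the labels. The labels name 2 genotypes, the wild type Col-0 and the arr10 arr12 double mutant, and 2 treatments, the cytokinin trans-zeatin and its solvent control DMSO, with 3 replicate arrays in each of the 4 groups. The titles of the treated arrays read CK for the wild type and TZ for the mutant, and both were taken as trans-zeatin. Per the labels' protocols, plants were grown for 2 weeks on vertical agar plates, RNA was extracted with an RNeasy kit, and biotin-labelled target was made by the manufacturer's procedure with a single amplification cycle. The extraction protocol speaks of harvested seedlings while the tissue label says roots, and the labels give neither the concentration of trans-zeatin nor the length of treatment.

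The deposited values are array signals in the unit intensity, on a linear scale, made with MAS5 and GCOS per the labels' processing notes; the versions of both are not given in the sources used here. Scaling by the authors was read from the values: the 2%-trimmed mean lay between 99.3 and 99.4 on every array, and the median signal of the probe sets other than controls lay between 39.3 and 41.6. The values were therefore used as deposited, with no further normalization. The table held 22810 probe sets, of which 64 controls were left out. The logarithm to base 2 was taken after adding an offset of 6.65, the 25th percentile of all remaining values. Fold changes below are on this scale, which understates the change of probe sets with low signal, and so sets the size of a difference between responses where 1 genotype has the lower signal. A probe set was tested when its mean over the 12 arrays lay above the 40th percentile, which corresponds to a signal of 23.1; 13647 probe sets passed. This filter removes genes that are dim in most groups even where they are bright in a single group, and such members of the gene lists are given from a fit without the filter and named as such.

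Probe sets were matched to genes through the platform annotation and the reference gene table. The annotation used here listed 14016 of the 22746 probe sets, 13513 of them with a single gene and 503 with several, and left 8730 without an entry. Of the tested probe sets, 7291 had a locus, from 7222 loci. Probe sets without an entry were tested like the others and are given by probe set identifier, with no gene name. ARR10, ARR12 and HKT1 had no probe set with an entry. Any probe set for them could not be told from the other unnamed ones, so none is given here under these names.

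Groups were compared with limma (version 3.58.1) in R (version 4.3.3): a linear model with a mean per group over all 12 arrays, moderated with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The 5 comparisons were trans-zeatin minus DMSO in each genotype, the difference between those responses (the interaction), and arr10 arr12 minus wild type under each treatment. The retained response in the mutant was measured as a slope through the origin of the mutant on the wild-type log2 fold change. For this, probe sets were chosen in a fit without 1 wild-type trans-zeatin array and 1 wild-type DMSO array, the wild-type fold change was taken from those 2 arrays, and the slope was averaged over the 9 possible choices. The labels do not say whether replicates came from separately grown plants, so the p-values measure the spread between these arrays, and the number of arrays limits their precision.

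The tests, the filter, the offset, the rule for naming genes and 28 gene lists were chosen before the data were examined. Named genes were the 10 largest rises and the 10 largest falls in each comparison among probe sets past the threshold, with a single gene, and with the 3 arrays of 1 group all above the 3 of the other, a condition not set for the interaction. Where fewer than 5 passed, the 5 with the smallest p were added and are said not to have passed. Up to 4 members of each list could be named whatever their result. Probe sets without a gene name, and the members of further gene groups given in the closing section, were chosen after their values were seen. Only 49 of the 383 genes on the lists had a probe set with an entry, 23 passed the filter and 26 lay below it. Of the 28 lists, 8 kept at least 2 members and were tested, 3 kept 1 member and 17 kept none. Lists were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation beside it, and with fry, with adjustment over the lists within each comparison.

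The test was tried on simulated data with 200 changed probe sets in each of 20 runs. Values were drawn from a normal distribution with each probe set's own mean and moderated residual SD. Probe sets and arrays were drawn independently, so the rates below hold without correlation between genes or arrays. In the wild-type response it called 63.9% of log2 changes of 0.5, 99.6% of those of 1 and 100% of those of 2, and 6.30% of its calls were false. In the interaction it called 20.3%, 92.4% and 100%, and 6.51% of its calls were false. The list test called 20 of 20 lists shifted by 0.5 at the preset correlation and 18 with an estimated one; of 140 lists without a shift it called 5 and 1. Simulated mutant responses equal in size to the wild type gave a mean slope of 0.911, and responses of a ratio of 0.5 gave 0.453, since noise in the held-out arrays lowers the slope. The ratio of medians gave 0.980 and 0.496. The simulated wild-type changes were those observed for called probe sets, which selection enlarges. These slopes may therefore be too high as a reference. Alternatives covered the offset, the filter, quantile normalization and median centring, the variance model, array weights, the arrays entering the fit, probe sets that can cross-hybridise, a minimum fold change and leaving out each array in turn.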

Results

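The data hold 12 arrays from roots of Arabidopsis thaliana, 3 for each combination of genotype and treatment. The wild type was Col-0. The mutant arr10 arr12 is named for lesions in ARR10 and ARR12, which are type-B response regulators, the transcription factors that act at the end of the cytokinin signalling relay. Roots had received trans-zeatin, a natural cytokinin, or DMSO, the solvent. The signal scale was alike on all arrays, with a median of 39.3 to 41.6. Correlation of log2 values across probe sets was 0.976 to 0.991 between arrays of a group and 0.958 to 0.988 between arrays of different groups. The first principal component, with 29.2% of the variance, set the 3 wild-type DMSO arrays apart, at 27.3, 18.4 and 14.5, with all other arrays at 3.70 or below. The second, with 22.2%, put the wild-type trans-zeatin arrays at 15.9 to 17.8 and the mutant DMSO arrays at -16.5 to -12.1.

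The first comparison asked how roots with both regulators respond to trans-zeatin. Transcripts of the CC-type glutaredoxins ROXY2 (AT5G14070; chromosome 5, 4541780 to 4542585, build TAIR10.1) and GRXS4 (AT4G15680; chromosome 4, 8931617 to 8932317), small thiol oxidoreductases, rose most among named genes above the filter. ROXY2 signal was 12.2, 20.2 and 22.3 on the 3 DMSO arrays (SD 5.35, n = 3) and 103 ± 24.1 under trans-zeatin, a log2 change of 2.15 ± 0.23 (SE; adjusted p = 2.6e-05). GRXS4 went from 24.1 ± 10.4 to 114 ± 39.6, a log2 change of 1.97 ± 0.25 (adjusted p = 1.2e-04). Other named genes that rose encode a dirigent-like protein (AT1G58170, 1.49), a member of the nitrate and peptide transporter family (AT3G45700, 1.43), a basic helix-loop-helix factor (AT4G25410, 1.43), acyltransferases of the BAHD family (AT2G40230, 1.41; AT3G50300, 1.40), a WD40 repeat protein (AT1G49450, 1.40) and a strictosidine synthase-like protein (AT3G57010, 1.37); AT3G46880 rose by 1.35. The genes that fell most were AT5G40590, with signal of 69.2 ± 5.08 under DMSO and 13.5 ± 1.69 under trans-zeatin (log2 change -1.91 ± 0.17, adjusted p = 8.6e-06), and AT5G62360, of the pectin methylesterase inhibitor family (-1.61 ± 0.16). Further falls were those of a galactose oxidase-like gene (AT1G19900, -1.44), an acyltransferase (AT5G01210, -1.43), a class III peroxidase (AT4G33420, -1.32), AT3G47510 (-1.32), AT2G22880 (-1.28), an AP2/ERF factor (AT5G07580, -1.25), AT1G19530 (-1.20) and GH3.3 (-1.18), which encodes an enzyme that conjugates auxin to amino acids. Among probe sets without a gene name, the largest changes were those of 264470_at (2.65), 259466_at (2.57) and 252374_at (2.32).

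In all, 506 probe sets rose and 661 fell with trans-zeatin in wild type, 1167 of the 13647 tested, and 105 of them changed at least 2-fold. The count was 740, 558 and 771 without trans-zeatin replicate 1, 2 or 3 of the wild type, and 735 and 659 without its DMSO replicate 1 or 2.

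The list of CC-type glutaredoxins does not hold ROXY2. Of its 4 members tested, 2 rose (GRXS4 and GRXS11, the latter by 0.47), GRXC14 fell by 0.74 (adjusted p = 0.038, lost in 7 other settings), and GRX480 did not pass (0.12). Adjusted over the list alone, the counts were 2 up and 1 down. The list as a whole did not pass with camera (adjusted p = 0.19); fry, which asks whether its genes moved one way on balance and compares them with no others, gave an adjusted p of 0.020. In the same comparison fry also passed for the auxin conjugation (0.015), root hair (0.015) and chlorophyll synthesis (0.044) lists. Of 3 genes for auxin conjugation, GH3.3 fell, GH3.17 rose by 0.59 and GH3.5 did not pass (-0.41); adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.26). UGT76C2, which encodes a cytokinin glucosyltransferase, rose by 0.54 (adjusted p = 0.048, lost in 14 of 23 other settings), and its neighbour UGT76C1 did not pass (-0.31). Adjusted over the list alone, 1 of this pair rose and 1 fell, with camera at adjusted p = 0.86.

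Both root hair genes tested fell in wild type, the expansins EXPA7 by 0.67 and EXPA18 by 0.43 (adjusted p = 0.046, lost in 12 of 23 other settings), and both passed adjusted over the list alone. This list passed with camera (adjusted p = 0.033) and was lost with an estimated correlation (adjusted p = 0.34 with an estimated correlation). LBD16, a transcription factor needed for lateral root initiation, fell by 0.95 ± 0.11 (adjusted p = 6.5e-05). PORB, which encodes protochlorophyllide oxidoreductase, fell by 0.92 (lost in 3 settings), and CHLM, of the same chlorophyll synthesis list, did not pass (-0.26); adjusted over the list alone both fell (camera adjusted p = 0.078). DFR, an enzyme of anthocyanin synthesis, fell by 0.76, and UF3GT did not pass (-0.42), also when adjusted over the list alone (camera adjusted p = 0.078). No member passed among the 3 cell cycle genes (AUR1, 0.14; MCM7, 0.25; AUR2, 0.25; camera adjusted p = 0.21) or the photosynthetic apparatus (RCA, -0.02; LHCB4.1, -0.16; camera adjusted p = 0.46), and none did adjusted over either list alone. IAA18 (-0.13) and GI (0.03), each the single tested member of its list, did not pass.

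Some cytokinin genes lay below the filter and were measured in the fit without it. The type-A response regulators, negative feedback regulators of cytokinin signalling and its classic early targets, were represented by ARR15 and ARR16, and both rose in wild type. ARR15 signal went from 10.5 ± 1.94 (SD, n = 3) to 59.2 ± 14.0, a log2 change of 1.92 ± 0.18 (adjusted p = 6.7e-05). ARR16 went from 7.96 ± 4.07 to 65.6 ± 5.40, a change of 2.34 ± 0.22 (adjusted p = 7.5e-05). In that fit 5 of the 12 glutaredoxins on the list rose and none fell, with 5 up and 1 down adjusted over the list alone; GRXS9 rose by 1.71, GRXS8 by 1.32 and GRXS5 by 0.92. LBD29, which acts with LBD16 in lateral root formation, fell as well (log2 change -1.20). The type-B regulators ARR18 (0.28), ARR19 (-0.08) and ARR23 (-0.08) did not pass.

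**Figure D1:**
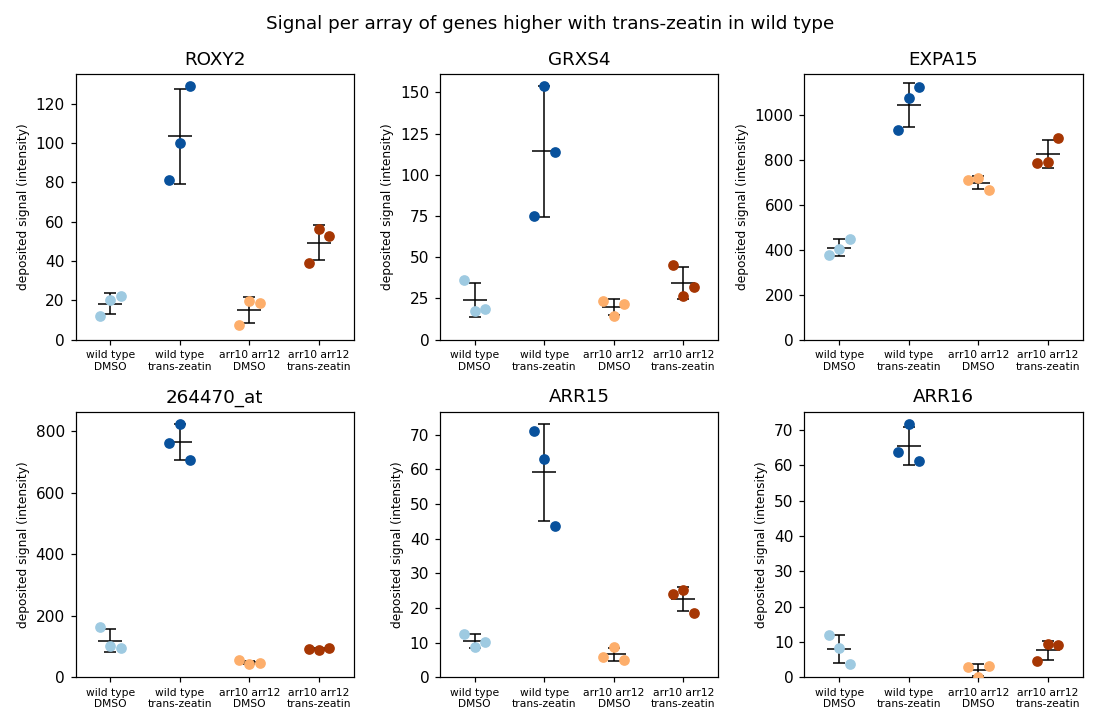
Deposited signal (intensity, linear axis from 0) of 6 probe sets on each of the 12 arrays, with points for arrays and black bars for the mean and SD of 3 arrays. ARR16 signal averaged 65.6 in wild-type roots with trans-zeatin and 7.68 in arr10 arr12 roots with trans-zeatin.

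The second comparison asked what response to trans-zeatin remained in arr10 arr12. ROXY2 rose here too, from 15.3 ± 6.61 (SD, n = 3) to 49.3 ± 8.93, a log2 change of 1.39 ± 0.23 (adjusted p = 0.0056). AT1G49450 (1.25), AT2G34610 (1.22), the acyltransferase gene AT5G47980 (1.21), AT1G64590 (0.94), AT4G25410 (0.88), AT3G45700 (0.85), AT4G02850 (0.78), AT4G03610 (0.75) and AT1G11670 (0.75) rose as well. The largest fall was that of ARL, a relative of the organ size gene ARGOS, from 117 ± 44.5 to 34.4 ± 8.11 (log2 change -1.54 ± 0.23, adjusted p = 0.0032). AT5G40590 (-1.47), the GH3-family gene AT1G48690 (-0.96), GH3.3 (-0.96), AT5G51440 (-0.95), AT1G19900 (-0.94), AT5G54040 (-0.83), AT1G29020 (-0.83), AT5G03230 (-0.82) and UGT76B1 (-0.82), a glucosyltransferase for salicylic and isoleucic acid, also fell. The probe sets 259466_at (2.16) and 252374_at (2.03) had the largest rises of all.

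In arr10 arr12, 84 probe sets rose and 79 fell, 163 in all, and 18 changed at least 2-fold. The count was 95 without trans-zeatin replicate 2 of the mutant and 64 and 59 without its DMSO replicate 2 or 3. Without mutant trans-zeatin replicate 1, 85 rose and 99 fell. Of the genes named here, AT2G34610, AT5G51440, AT1G19900, AT5G54040, AT1G29020 and AT5G03230 were each lost in at least 1 of these or other settings.

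On the gene lists, GH3.17 rose by 0.49 (adjusted p = 0.031, lost in 10 of 23 other settings), GH3.3 fell, and GH3.5 did not pass (-0.32); adjusted over the list alone, 1 rose and 2 fell. LBD16 fell by 0.61 (adjusted p = 0.010, lost in 3 of 22 other settings). ROXY2, which rose, is not on the glutaredoxin list. None of the 4 members of that list passed, among them GRXS4 at 0.63 and GRXS11 at -0.01, and none did adjusted over the list alone. EXPA7 (-0.19), EXPA18 (0.02), PORB (-0.44) and DFR (-0.52) did not pass, although DFR did adjusted over its list alone, as did UGT76C2 (0.47). No list passed with camera, where the smallest adjusted p was 0.46. In the fit without the filter, ARR15 rose by 1.15 ± 0.18 (adjusted p = 0.014, lost in 3 settings), GRXS9 rose by 1.00 (lost in 1 setting), LBD29 fell by 0.85 (adjusted p = 0.039, lost in 13 settings), and ARR16 did not pass (0.71 ± 0.22, adjusted p = 0.25).

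The responses of both genotypes, which share no arrays, pointed the same way. Of the 163 probe sets called in arr10 arr12, 71 rose and 69 fell in both genotypes and 0 went opposite ways, where 3.11 and 3.83 were expected if the calls were independent. Of the 1167 called in wild type, 994 (85.2%) had the same sign in the mutant, and 1122 had a smaller change there; these counts favour the wild type, since its own arrays chose the probe sets. With held-out arrays the slope of the mutant on the wild-type change was 0.510 on average (0.492 to 0.540 over the 9 choices), against 0.911 for equal responses in simulated data. That reference may be too high, since the simulated wild-type changes were enlarged by selection. The median change in the direction of the wild-type call was 0.60 in wild type and 0.32 in arr10 arr12, a ratio of 0.538.

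The interaction tested directly whether the response differed between genotypes, and 5 probe sets passed. The single named gene was EXPA15 (AT2G03090; chromosome 2, 916806 to 918671, build TAIR10.1), which encodes an expansin, a protein that loosens cell walls. Its signal rose from 409 ± 36.8 (SD, n = 3) to 1043 ± 98.9 in wild type and was 698 ± 28.2 and 824 ± 62.7 in the mutant. The difference of the responses was -1.10 ± 0.13 (adjusted p = 0.0031), and its level under DMSO was already higher in the mutant, by 0.76 (adjusted p = 3.9e-04). The other 4 were 264470_at (-1.80), 252858_at (-1.39), 264790_at (-1.26) and 267461_at (0.88), none with a gene name and all chosen after their values were seen. The next named genes did not pass: AT3G45680, of the nitrate and peptide transporter family (-0.85, adjusted p = 0.072), AT2G40230 (-0.93, 0.10), AT2G32220 (-0.80, 0.11), AT5G62360 (1.14, 0.11) and AT1G08590 (-0.71, 0.11), a receptor-like kinase gene.

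Of the 5 calls, 267461_at was lost in 9 of 22 other settings, and without mutant trans-zeatin replicate 2 the count was 9. On the lists, the root hair genes EXPA7 and EXPA18 (median 0.46) lay at the threshold with camera (adjusted p = 0.0499; adjusted p = 0.46 with an estimated correlation). The list passed in 5 of 16 other settings (adjusted p from 0.0072 to 0.18). Neither gene passed by itself, and both did adjusted over the list alone, as did GRXS4 (-1.34) and GRXS11 (-0.47) on theirs. ARR16 had an interaction of -1.63 ± 0.31 in the fit without the filter and did not pass (adjusted p = 0.21), nor did ARR15 (-0.77, adjusted p = 0.41). Their signals in mutant DMSO roots, 2.13 and 6.56, lay below the offset, which therefore sets the size of both values.

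The fourth comparison asked how arr10 arr12 roots differed from wild type under DMSO alone. Transcripts for the late steps of anthocyanin synthesis were the named genes that were lower by most. DFR (AT5G42800; chromosome 5, 17164093 to 17166032, build TAIR10.1), which encodes dihydroflavonol reductase, had signal of 329 ± 77.5 (SD, n = 3) in wild type and 39.9 ± 13.1 in the mutant, a log2 difference of -2.86 ± 0.19 (adjusted p = 2.1e-07). UF3GT, an anthocyanin glycosyltransferase gene, differed by -2.49 ± 0.24 (178 ± 77.2 against 24.9 ± 5.66), and AT4G14090, another anthocyanin glucosyltransferase gene, by -2.14 ± 0.24. The flavonoid list, DFR and UF3GT, passed with camera (adjusted p = 1.4e-07) and with an estimated correlation (adjusted p = 0.018, and up to 0.051 in other settings); both members were lower, also adjusted over the list alone. A berberine bridge enzyme-like gene (AT1G26390, -1.41), AT1G05340 (-1.33), the AP2/ERF factor gene ORA47 (-1.12), the peroxidase genes AT2G39040 (-1.11) and AT5G64110 (-1.07), AT5G38980 (-1.10) and AT1G14960 (-1.07) were lower as well. Higher in the mutant were the lipid-transfer family genes AT4G12500 (1.33; 26.1 ± 5.19 against 74.9 ± 1.61) and AT4G12490 (0.83), the germin-like gene AT5G38910 (1.32), a GDSL lipase gene (AT1G29660, 1.28), AT1G09310 (1.11), a phosphoethanolamine methyltransferase gene (AT1G73600, 1.06), AT2G25510 (1.01), AT5G52790 (0.88), AT1G73620 (0.79) and AT4G29020 (0.78). The largest differences of all were those of 253500_at (-4.18) and 264374_at (-4.01), neither with a gene name. Their mutant signals of 3.52 and 3.00 lay below the offset of 6.65, so the offset sets the size and order of these values, which understate the difference.

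Genes of the photosynthetic apparatus were lower in the mutant, RCA (rubisco activase) by -0.55 and LHCB4.1 (a light-harvesting protein) by -0.56. Both passed adjusted over the list alone, and the list passed with camera (adjusted p = 7.2e-04). With an estimated correlation it had an adjusted p of 0.040 and passed in 4 of 16 other settings (0.019 to 0.076). On the chlorophyll synthesis list PORB was lower (-0.82, adjusted p = 0.049) and CHLM did not pass (-0.40), though adjusted over the list alone both were lower; the list passed with camera (adjusted p = 0.011) and was lost with an estimated correlation (adjusted p = 0.13 with an estimated correlation). The root hair genes EXPA7 (-0.55) and EXPA18 (-0.49) were lower, both also adjusted over the list alone, and their list passed with camera (adjusted p = 0.0056) and was lost with an estimated correlation (adjusted p = 0.11 with an estimated correlation). No member passed among the glutaredoxins (GRX480, -0.50), the auxin conjugation genes (GH3.3, 0.42), the cytokinin glucosyltransferases (UGT76C2, -0.43) or the cell cycle genes (MCM7, 0.35); adjusted over each list alone, UGT76C2 was lower and 2 cell cycle genes were higher. In the fit without the filter, GRXS9 was lower (-0.58, adjusted p = 0.044, lost in 11 of 21 other settings).

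Under DMSO, 270 probe sets were higher and 401 lower in arr10 arr12, 671 in all, and 43 differed at least 2-fold. The count was 207 and 232 without wild-type DMSO replicate 1 or 2, and 163 and 173 without mutant DMSO replicate 1 or 2. Without wild-type DMSO replicate 3 it was 901, with 453 higher and 448 lower, so the excess of lower probe sets was not kept. With array quality weights it was 1307, with 628 higher and 679 lower, and without wild-type trans-zeatin replicate 2, 163 were higher and 291 lower. Without some of the 4 arrays that reduced the count most, ORA47, AT5G64110, AT4G12490, RCA, PORB, EXPA7 and EXPA18 no longer passed.

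**Figure D2:**
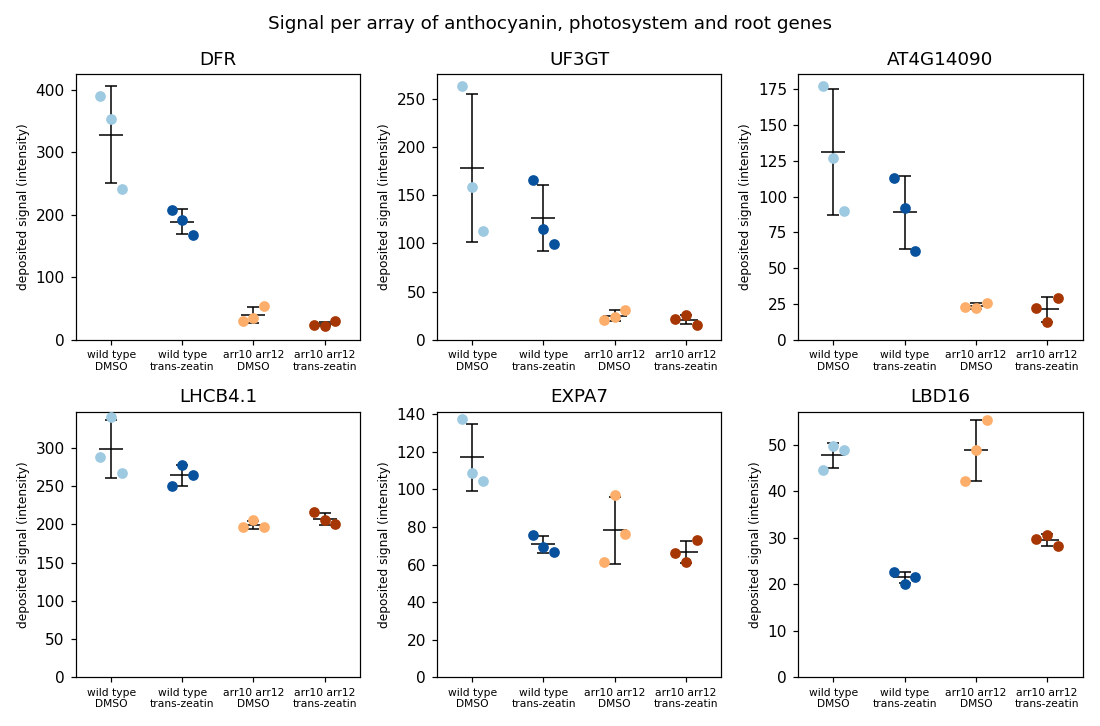
Deposited signal (intensity, linear axis from 0) of 6 genes on each of the 12 arrays, with points for arrays and black bars for the mean and SD of 3 arrays. DFR signal averaged 329 and 189 in wild type and 39.9 and 25.2 in arr10 arr12, under DMSO and trans-zeatin.

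The last comparison asked the same under trans-zeatin. The anthocyanin genes were again lower in the mutant, DFR by -2.62 ± 0.19 (adjusted p = 7.8e-07), UF3GT by -2.26 ± 0.24 and AT4G14090 by -1.80 ± 0.24. The flavonoid list passed with camera (adjusted p = 9.7e-09) and with an estimated correlation (adjusted p = 0.012), and both members were lower adjusted over the list alone. Genes that had risen in wild-type roots were lower in the mutant: GRXS4 by -1.53 ± 0.25 (114 ± 39.6 against 34.5 ± 9.78; SD, n = 3), AT3G57010 by -1.19, and AT3G45680 by -1.20. The peroxidase genes PRX52 (-1.54), AT5G06730 (-1.32) and AT5G64110 (-1.22) and ARL (-1.29) were lower too. Higher were the germin-like gene AT5G38910 (1.47), AT1G49470 (1.26), AT5G43180 (signal of 402 ± 24.1 against 172 in wild type), the peroxidase genes AT4G33420 (1.17), AT5G15180 (1.02) and AT2G41480 (1.00), AT1G31050 (1.14), AT4G12500 (1.07), AT1G29660 (0.99) and AT4G12490 (0.99). The probe sets 264374_at (-4.90), 253500_at (-4.03) and 264470_at (-2.97) had the largest differences, and the mutant signals of 2.30 and 7.40 for the first pair, near or below the offset, again leave their size and order to it.

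On the lists, GRXS4 was the single glutaredoxin of the 4 on the list that passed, with GRXS11 at -0.33, and both were lower adjusted over the list alone. The list passed with camera (adjusted p = 0.035) and was lost with an estimated correlation (adjusted p = 0.14 with an estimated correlation). RCA was lower (-0.50, adjusted p = 0.026), LHCB4.1 did not pass (-0.34), and both were lower adjusted over the list alone; this list passed with camera (adjusted p = 0.0027) and was lost with an estimated correlation (adjusted p = 0.064 with an estimated correlation). GH3.3 was higher by 0.64 (adjusted p = 0.044, lost in 11 of 22 other settings). The root hair, chlorophyll synthesis, cytokinin glucosyltransferase and cell cycle lists had no member past the threshold, where UGT76C2 (-0.50) was lower adjusted over the list alone. In the fit without the filter, ARR16 was lower by -2.35 ± 0.22 (adjusted p = 1.2e-04), ARR15 by -1.16 ± 0.18 (adjusted p = 0.0066) and GRXS9 by -1.29 ± 0.13 (adjusted p = 2.8e-04). Over all comparisons 9 list tests passed with camera, and 3 of them also passed with an estimated correlation. These were the flavonoid list under trans-zeatin, which did so in all 16 other settings, the flavonoid list under DMSO, in 15 of 16 (highest adjusted p 0.051), and the photosynthetic apparatus under DMSO, in 4 of 16. The 9 include the root hair list in the wild-type response, the interaction and the genotype difference under DMSO. All of those comparisons use the wild-type DMSO arrays, so they are not separate results for this list. In the comparisons without these arrays its median was -0.09 (response of arr10 arr12) and -0.06 (genotypes under trans-zeatin). In both genotype comparisons fry passed for the lists that passed with camera and for auxin conjugation (adjusted p = 0.044 under DMSO and 0.021 under trans-zeatin), and in the mutant response and the interaction it passed for none.

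Under trans-zeatin 117 probe sets were higher and 192 lower in the mutant, 309 in all, and 44 differed at least 2-fold. Without wild-type trans-zeatin replicate 1, 2 or 3 the count was 191, 151 and 192, and AT3G57010 and RCA no longer passed without some of these. The genotype differences under DMSO and under trans-zeatin, which share no arrays, had 28 higher and 92 lower probe sets in common and 0 opposite ones, where 2.31 and 5.64 were expected if the calls were independent. Here too both tests use the same estimate of spread per probe set, so the expected counts may be too low.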

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

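The tests of selection and of a single array, and the counts over other groupings, were chosen before the result was seen, and the test of the wild-type DMSO arrays was chosen after it. The response to trans-zeatin differed between genotypes for 5 probe sets by the interaction test, as arr10 arr12 response minus wild-type response. It was -1.80 ± 0.22 (SE) for 264470_at, which rose by 2.65 in wild type and 0.85 in the mutant (adjusted p = 0.0031). It was -1.10 ± 0.13 for EXPA15, with 1.33 in wild type and 0.24 in the mutant, where the gene did not pass (adjusted p = 0.0031). It was -1.39 ± 0.18 for 252858_at, with 1.57 and 0.18, and -1.26 ± 0.16 for 264790_at, with 1.93 and 0.67 (adjusted p = 0.0033 for both). It was 0.88 ± 0.14 for 267461_at, which fell by 0.71 in wild type and was at 0.18 in the mutant (adjusted p = 0.021).

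Over 100 of the 200 ways to regroup the arrays within each treatment, 5 gave 5 or more probe sets, the real one included, so by the count of groupings chance is not excluded for this result. The highest other value was 939. That grouping exchanges the genotype labels among the trans-zeatin arrays, so it measures the lasting difference between genotypes, a structure of the samples and not a noise level. Without it, a step taken only after its value was seen, 4 of 99 groupings gave 5 or more and the highest other was 46. In 88 groupings the count was 0, but groupings that mix the genotypes hold the genotype difference as spread.

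Across probe sets called in wild type, the response in arr10 arr12 was smaller, with a held-out slope of 0.510; of the 163 probe sets called in arr10 arr12 itself, 112 had a larger change in wild type. Choosing probe sets on the arrays that also measured them is argued against, since the highest slope over the 9 held-out choices was 0.540. Simulated equal responses gave 0.911, which may be too high a reference. A single mutant array is argued against as well, since the mean slope without each of the 6 in turn reached at most 0.561. A state of the wild-type DMSO arrays unrelated to trans-zeatin was tested on probe sets that respond in the mutant, chosen on mutant arrays and measured on held-out ones. The ratio of the mutant to the wild-type change was 0.647 on average and at most 0.786 over 9 choices. It was at most 0.765 over the 6 that did not have to be filled up to 50 with uncalled probe sets. The same wild-type DMSO arrays entered the wild-type change in every choice. The ratios therefore argue only against a state that moved these probe sets with no shared direction. A state that set them opposite to trans-zeatin would lower the ratio too, so it stays open. For probe sets that respond in wild type alone, a state of either kind stays open. A reduced cytokinin response without ARR10 and ARR12 is a hypothesis consistent with these values; a state of the wild-type DMSO roots that resembles less cytokinin stays open, as does any difference in growth or harvest between genotypes, which the design confounds with genotype.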

How the results depend on the processing

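All settings here were chosen before the data were examined, except those for the gene groups added afterwards. For the wild-type response, array quality weights gave 2193 probe sets, the 2-fold minimum 105, and leaving out 1 array in turn 558 to 1355. For the response in arr10 arr12, no filter gave 102, the compared arrays alone 76, the 2-fold minimum 18, and leaving out 1 array 59 to 188. For the interaction, array quality weights gave 22 and leaving out 1 array 4 to 9. For the genotype difference under DMSO, no filter gave 420, array quality weights 1307, the 2-fold minimum 43, and leaving out 1 array 163 to 901. For that under trans-zeatin, the 2-fold minimum gave 44 and leaving out 1 array 151 to 361. The mean slope was 0.493 with array quality weights and 0.466 to 0.561 without each mutant array. The 9 list calls became 3 with an estimated correlation and 6 to 12 without 1 array. A fold minimum can only remove calls; for the other settings, where leaving out an array raised some counts and lowered others, the cause was not tested. Apart from the block by replicate number, all other total counts stayed within 1.5 times those reported. The balance of directions moved more: the excess of lower probe sets under DMSO was gone without wild-type DMSO replicate 3 (453 higher, 448 lower) and small with array quality weights (628 higher, 679 lower). In the response of arr10 arr12, 72 rose and 74 fell without the variance trend, 81 rose and 81 fell with the larger offset, and 85 rose and 99 fell without its trans-zeatin replicate 1. With the 2-fold minimum 53 rose and 52 fell in wild type. The medians of 5 lists that had not passed changed sign in 1 setting each.

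The main model had no block by replicate number. Residuals of same-number arrays correlated at -0.072 to 0.337, with a mean of 0.107 and 9 of 18 pairs over 0.1. Not every same-number pair correlated, which does not exclude shared handling. The mean for other numbers was -0.053, which is no separate comparison, since residuals cancel out within each group. Of the 12 arrays, 9 correlated best with an array of their own number, a hint from the data of shared handling that stays open. A block by replicate number gave 1399, 284, 7, 919 and 471 probe sets for the 5 comparisons in the order of the report, a slope of 0.492 and 10 list calls. The probe set counts were each above those of the main model. With this block the glutaredoxin list under trans-zeatin no longer passed with camera (adjusted p = 0.083). With an estimated correlation neither the flavonoid list (0.051) nor the photosynthetic apparatus (0.053) passed under DMSO. The chlorophyll list passed with camera in the wild-type response (adjusted p = 0.024) and the interaction (0.034). It passed in neither with an estimated correlation (0.28 and 0.27).

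Of 146 single results, 141 were called; 109 of these kept their call in every setting run for them, 32 lost it in at least 1, and 0 reversed their direction. Scaling moved the median of all probe sets by at most 0.035. Probe sets under a signal of 23.1 were not tested, and changes of 0.5 on the log2 scale are often missed (63.9% found in simulated wild-type responses, 20.3% in the interaction).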

Other observations

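The gene groups in this part, the tests of wounding and low oxygen and of separate control arrays, and the tests of shoot tissue and RNA degradation were chosen after the result was seen. The other tests were chosen before. The test of a single array for plastid-encoded and nuclear genes still concerns gene groups chosen afterwards, so its pattern was not fixed in advance. In wild-type roots with trans-zeatin, 13 of 41 class III peroxidase genes fell and 2 rose, with a median of -0.23. AT4G33420 (-1.32), AT5G19890 (-0.80) and AT5G64120 (-0.73) fell, and AT2G34060 (1.03) and AT2G43480 (0.63) rose. Of 17 core low-oxygen genes, 6 fell and 1 rose (median -0.41), among them AT1G19530 (-1.20) and CML38 (-0.89). Of 8 rapid wound and touch genes, 4 fell and none rose (median -0.51), namely AT2G22880 (-1.28), CML38, STZ (-0.72) and CML42 (-0.59). Of 10 tau-class glutathione transferase genes 5 fell and 1 rose (GSTU27, -0.84; GSTU26, 0.55). These groups passed with camera: adjusted p = 4.0e-05 for the peroxidases and for the wound genes, 3.1e-04 for the low-oxygen genes and 0.0022 for the glutathione transferases. None of them passed with an estimated correlation (adjusted p = 0.18 for the peroxidases, low-oxygen genes and glutathione transferases, and 0.24 for the wound genes). The groups described here are a choice among more that were tested. Others also passed with camera, among them genes with symbols beginning with ATG (adjusted p = 0.019) and CYP (0.036) in this comparison. Between genotypes, so did BGLU (0.013) and SCPL (0.034) under DMSO, and BGLU (0.0093) under trans-zeatin. None of these passed with an estimated correlation. Against the same wild-type DMSO arrays, arr10 arr12 under DMSO also had 9 lower peroxidase genes (median -0.22). It had 4 lower low-oxygen genes (median -0.32) and 2 lower wound genes (median -0.67). In that order, the groups had adjusted p = 7.6e-05, 0.0050 and 8.9e-04 with camera, and 0.15, 0.24 and 0.44 with an estimated correlation. In the response of arr10 arr12, against its own DMSO arrays, no member of these 3 groups passed, while the peroxidases and low-oxygen genes passed as groups with camera (adjusted p = 0.012 and 0.011, each 0.50 with an estimated correlation). High values on the wild-type DMSO arrays therefore stay open as a part of the falls in wild type.

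Expansin genes went both ways in wild type: EXPA15 (1.33), EXPB1 (1.03) and EXPA8 (0.73) rose, and EXPA7 (-0.67), EXLB1 (-0.60) and EXPA18 (-0.43) fell, of 13 tested. Of 28 glycosyltransferase genes of the UGT family, 4 rose and 6 fell, and their median (0.11) and camera's direction (down) differed in sign. UGT76D1 rose by 0.61 and UGT78D1, a flavonol glycosyltransferase gene, by 0.49, and UGT71C3 (-0.70) and UGT88A1 (-0.70) fell.

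The wild-type response and the genotype difference under DMSO pointed the same way, with 70 probe sets higher and 139 lower in both, where 10.0 and 19.4 would be expected of independent calls, and 23 opposite. Both are measured against the same 3 wild-type DMSO arrays, so part of this excess may come from chance values of those arrays. The estimate of spread that both tests share may add to it. The covariance of the log2 changes was 0.0299, above the highest of 100 simulations without effect (0.0250), but without wild-type DMSO replicate 1 it was 0.0256, below the highest of 0.0330 for 2 control arrays; the correlation of 0.459 was close to the simulated mean of 0.471. With the control arrays parted so that each comparison had its own, the covariance was 0.0127 to 0.0255 over the 6 ways (SD 0.0044), and its lowest value exceeded the highest such value of 100 simulations (0.0124) by less than the spread between the ways; with replicates 2 and 3 as separate controls the lower value was 0.0138, against 0.0145. Chance values of the shared arrays and that replicate alone therefore cannot be told apart from a state of all wild-type DMSO plants, nor can wounding or low oxygen of them: both lists had negative medians in both comparisons, and the highest adjusted p with an estimated correlation was 0.437.

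Under DMSO, nuclear genes for light harvesting and photosystems were lower in arr10 arr12 (6 of 7, median -0.60, adjusted p = 0.091 with an estimated correlation), among them LHCB4.2 (-0.86) and PSAE-1 (-0.85). Plastid-encoded genes were not: 5 of 56 were higher, such as psaA (0.71), and 0 lower (median 0.28, adjusted p = 0.54 with an estimated correlation). A smaller share of shoot tissue was assumed to lower both sets, which was not tested on these arrays. It cannot be told apart from the genotype: the plastid-encoded median stayed positive without each array, but fell to 0.121 without wild-type DMSO replicate 1. The plastid-encoded values per array overlapped (0.11 to 0.18 on the centred scale in mutant DMSO, -0.42 to 0.16 in wild type). A single array is argued against by the gap between the medians, which was at least 0.764 without each array. RNA degradation cannot be told apart from the genotype, since the 3' to 5' signal ratios of the control genes differ in what they show. The mean log2 ratio of GAPDH was -0.104 different in mutant DMSO arrays. That of actin was 0.55 higher (3.33 in wild type, 3.88 in the mutant), and the ranges overlapped for both genes. The low wild-type mean of actin rested on DMSO replicate 1, at 2.59, with the other wild-type DMSO arrays at 3.51 or above. That replicate also had the highest value on the first principal component (27.3). Without it 207 probe sets passed between genotypes under DMSO in place of 671, and leaving out other single arrays gave as few as 163. In wild type with trans-zeatin 3 of the 7 nuclear genes fell (median -0.43, adjusted p = 0.18 with an estimated correlation), with a mean centred value of 0.042 against 0.49 under DMSO. Between genotypes under trans-zeatin 1 of 7 was lower (median -0.43, adjusted p = 0.20 with an estimated correlation), and the plastid-encoded median was 0.01. The centred values of the nuclear genes per array did not overlap there: -0.02 to 0.08 in wild type and -0.56 to -0.25 in the mutant. The nuclear values under trans-zeatin argue against high wild-type DMSO arrays as the whole account, since no such array enters that comparison. For the difference under DMSO, high values on those arrays stay open beside an effect of the genotype, which is a hypothesis. A difference in light or handling between genotypes is untested.

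Each comparison of 3 arrays with 3 has 10 groupings, too few for a share under 0.05. The real grouping was in each case the 1 with the most probe sets: 1167 against a highest other of 0 for the wild-type response, 163 against 1 for arr10 arr12, 671 against 0 under DMSO and 309 against 0 under trans-zeatin. Every other grouping mixes both groups, so a real difference enters its spread and lowers its count, which is therefore no noise level.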
